A study of Populus tremula x Populus alba with 6 samples.

How the data were processed

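Polyadenylated RNA from the shoot apex of 6 hybrid poplars was sequenced as paired-end, strand-specific libraries with a TruSeq stranded mRNA protocol, per the labels' protocols. The libraries fall into 3 wild-type controls (CTRL) and 3 plants carrying an RNAi construct against DDM1 (RNAi), and the series' design text calls the 3 of each group biological replicates. The deposited values are raw gene counts, 1 file per library, with a column each for counts taken without regard to strand, on the forward strand and on the reverse strand, per the file headers. STAR is the only tool that the submitters' processing notes name. Its version, the genome build and the annotation are not given in the sources used here, and neither is any filter on genes.

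The counts of the reverse column were used, because this kit places sense reads there. The forward column, taken here as the strand opposite to each gene, held between 1.59% and 1.82% of the counts on both strands. Each file lists 32049 genes, of which 2253 had 0 counts in all 6 libraries. The summary lines for unmapped, multimapping, no-feature and ambiguous reads, the last 2 taken from the reverse column, name no gene and stayed out of library sizes and tests. They held between 11.7% and 13.1% of the reads of a library. Counts assigned to genes ranged from 12399644 to 17165295 per library, so that a count of 0, which allows up to 3 counts, sets a limit between 0.173 and 0.260 CPM (counts relative to the TMM-scaled library size). Such limits and the counting intervals cover counting error only. All pairs of libraries differed by more than sampling noise (chi-square per degree of freedom between 8.31 and 40.9), and none was treated as a duplicate.

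RNAi was compared with CTRL by edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust fit, two-sided) with trimmed-mean (TMM) factors and the filterByExpr filter, which left 24991 genes. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of F. Counts were simulated for this comparison over 24991 genes with 200 changed, drawn independently per gene and library from the fitted dispersions. On them the test recovered 37 of 67 genes changed by 2-fold, 58 of 67 changed by 4-fold and 63 of 66 changed by 8-fold. It also called 17 unchanged genes. No structure among libraries was simulated, so recovery in the real libraries may be lower. The fit, its filter and the alternatives were set before the data were examined. These alternatives were DESeq2 1.42.0, edgeR's likelihood ratio test, limma-voom (limma 3.58.1), other normalization factors, other filters, the replicate number as a block, a fold threshold, the other count columns and leaving out each library. A fit with 1 surrogate variable (sva 3.50.0), DESeq2 on the genes that edgeR tested, a fit that was not robust, and all analyses of read classes, chromosome groups, neighbouring genes, genes at 0 in 1 group and genes with a fitted change of 4-fold or more were chosen after seeing the data.

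The files do not pair gene identifiers with names and no annotation was used. The level of DDM1, the lists of gene families set beforehand and the transposon-derived genes were therefore not analysed here. The rule for named genes in this case takes the 2 identifiers with the largest fitted increase in RNAi and the 2 with the largest fitted decrease among the tested genes, whether or not they passed the test. Any other identifier was chosen after its values were seen. Chromosomes are read from the number in the identifier, as poplar loci are named, and neighbours are neighbours in identifier order. Genes without a chromosome number form 1 scaffold group. The 20 groups so formed were tested with camera (preset correlation of 0.01, on log2 CPM with a prior count of 2), and again with an estimated correlation and with fry. Neighbouring genes were scanned for runs of 5 to 30 tested genes by the sum of their signed, rank-normalized test statistics divided by the square root of the run length, against 1000 random gene orders. Read-class shares were compared by exact two-sided permutation tests, in which 3 against 3 libraries cannot reach a p below 0.10.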

Results

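Transcript levels in the shoot apex, the growing tip that holds the shoot meristem and the youngest leaves, were measured by RNA sequencing in 6 plants of the poplar hybrid Populus tremula x Populus alba. Of these plants, 3 were wild type (CTRL) and 3 carried an RNAi construct against DDM1 (RNAi), a gene for a chromatin remodeller that plants need to maintain DNA methylation, chiefly in transposons. All 6 had 3 weeks of water deficit and then 1 week of re-watering, at 21 °C with 16 h of light. The comparison therefore asks how apices carrying the construct differed from wild-type apices after the same drought, and holds no contrast of watered and droughted plants. Sequencing depth was 14054541, 15731391 and 17727452 reads in CTRL 1, 2 and 3 and 16093955, 18083152 and 19545759 reads in RNAi 1, 2 and 3. Between 86.9% and 88.3% of the reads of a library were assigned to genes on the sense strand. The level of DDM1 itself was not analysed here, because the files do not pair gene identifiers with names. The knock-down therefore rests on the labels. Whether the 3 RNAi plants came from 1 transformed line or several did not enter the comparison. It therefore cannot tell effects of a line from those of the knock-down. Between 28045 and 28588 genes had at least 1 count in a library.

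Between RNAi and wild-type apices 1 gene of 24991 tested was called changed. This gene, Potri.016G130900 on chromosome 16, rose from a total of 1 count over the 3 CTRL libraries to 46, 70 and 78 counts in RNAi 1, 2 and 3. Its level was 4.10 ± 0.67 CPM in RNAi against 0.02 ± 0.04 CPM in CTRL (SD, n = 3 each). The ratio of the pooled counts was 176, with a 95% exact interval from 31.2 to 6973 that covers counting error only. With 1 CTRL count the fitted log2 fold change depends on the prior count, and its SE spans less than this counting interval. The fitted value was 7.01 ± 0.59 (SE), with an adjusted p of 0.047 in edgeR's quasi-likelihood test. The next lowest adjusted p among all genes in that test was 0.21. The call was lost when any library but RNAi 1 was left out, with adjusted p in edgeR between 0.16 and 0.67, and no gene then passed the threshold. Without CTRL 2 its log2 fold change was 8.94, and without RNAi 1, 7 genes were called, 1 higher and 6 lower. On all 6 libraries the call was lost with library size as the only scaling (adjusted p = 0.0564 in edgeR), with a filter of at least 1 CPM in 3 libraries (0.0501) and with 1 surrogate variable (0.0934).

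The other named gene that was higher in RNAi, Potri.018G050400 on chromosome 18, had 0 counts in all 3 CTRL libraries and 14, 17 and 21 counts in the RNAi libraries. Its fitted log2 fold change of 7.05 depends on the prior count, and its order with that of Potri.016G130900 turned in DESeq2, in limma-voom and without CTRL 2 or RNAi 1. Against a floor of 3 counts over the CTRL group its level was at least 15.7-fold higher in RNAi, at 1.10 ± 0.10 CPM (SD, n = 3). This floor leaves out the counting error of the RNAi counts, with which the 95% exact interval of the ratio starts at 12.3. It did not pass the threshold in edgeR's quasi-likelihood test (adjusted p = 0.46), but did in DESeq2 (adjusted p = 0.0028) and limma-voom (adjusted p = 0.017). The 2 largest fitted differences downwards were those of Potri.016G070100 on chromosome 16 and Potri.019G008300 on chromosome 19, neither of which passed the quasi-likelihood test. Potri.016G070100 had 33, 14 and 57 counts in CTRL and 3, 0 and 0 counts in RNAi, a CTRL to RNAi ratio of 38.3 with a 95% exact interval from 12.7 to 189 (adjusted p = 0.61 in edgeR's quasi-likelihood test, 0.0010 in DESeq2). Potri.019G008300 had 36, 19 and 121 counts in CTRL and 9, 0 and 1 counts in RNAi, or 3.96 ± 3.15 CPM against 0.24 ± 0.36 CPM (SD, n = 3 each, adjusted p = 0.80 in edgeR). Of the RNAi counts, 3 of 3 and 9 of 10 came from RNAi 1, without which the fitted log2 fold changes went from -5.07 to -8.21 and from -4.14 to -6.70. That of Potri.016G070100 was -4.46 without RNAi 3, and that of Potri.019G008300 was -3.27 without CTRL 3, which held 121 of its 176 CTRL counts. For all 4 genes the CPM values of the 2 groups did not overlap, which their choice by the largest fitted difference favours.

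**Figure D1:**
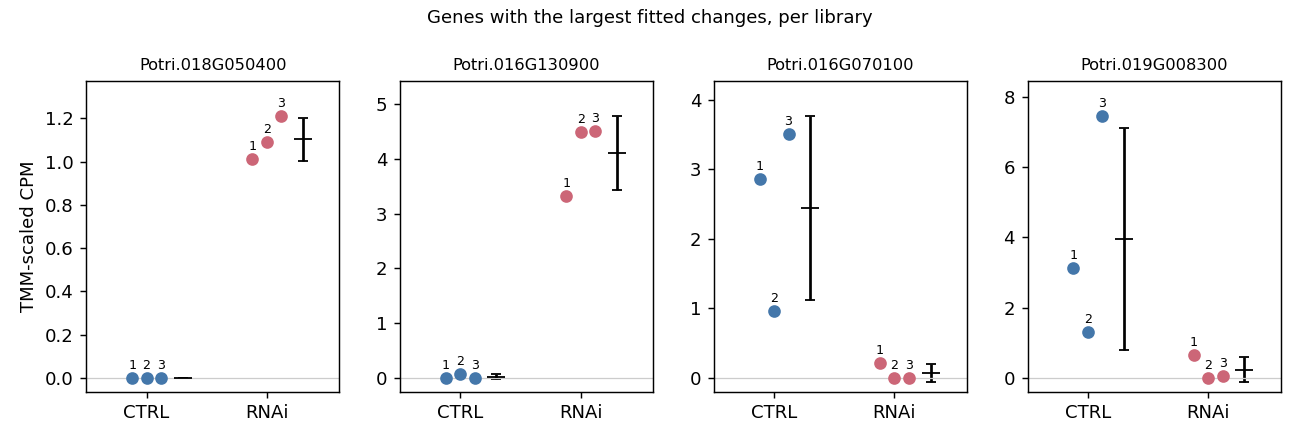
Level of the 4 named genes in each library, as TMM-scaled CPM (vertical axes, linear, 1 per gene), for CTRL (blue) and RNAi (red) replicates 1 to 3, with the mean and SD of each group as a black bar. Potri.018G050400 and Potri.016G130900 were at or near 0 in CTRL and present in all 3 RNAi libraries, and in the other 2 genes, lower in RNAi, RNAi 1 lay above RNAi 2 and RNAi 3.

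No gene was called lower in RNAi. At an unadjusted p under 0.05 edgeR's quasi-likelihood test gave 769 genes higher and 641 lower in RNAi, a total of 1410 where the threshold alone gives about 1250. Other groupings of the same 6 libraries gave totals between 214 and 2966, and without CTRL 3 the total was 733. DESeq2, with its own size factors and filtering, called 18 genes higher and 19 lower, and on the 24991 genes that edgeR tested 19 higher and 19 lower. On these genes too, edgeR's likelihood ratio test called 29 higher and 32 lower and limma-voom 2 higher and 0 lower. The CTRL and RNAi CPM values did not overlap in 2956 genes, 11.8% of those tested, where chance gives 10%. The spread between replicates corresponded to a biological coefficient of variation of 0.20.

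On the first principal component, which held 35.4% of the variance, all 3 CTRL libraries (-34.1 to -14.6) lay below all 3 RNAi libraries. RNAi 2 stood apart there, with a score of 63.75 against 8.88 for RNAi 3 and -6.49 for RNAi 1. Chance alone parts 3 against 3 libraries on an axis in 10% of cases, so this order does not tie the component to the genotype. On the second component, with 28.6% of the variance, CTRL 2 (34.3) lay beside RNAi 3 (34.6), and CTRL 1 (-44.2) and RNAi 1 (-19.0) were the lowest, so that this component did not part the groups.

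**Figure D2:**
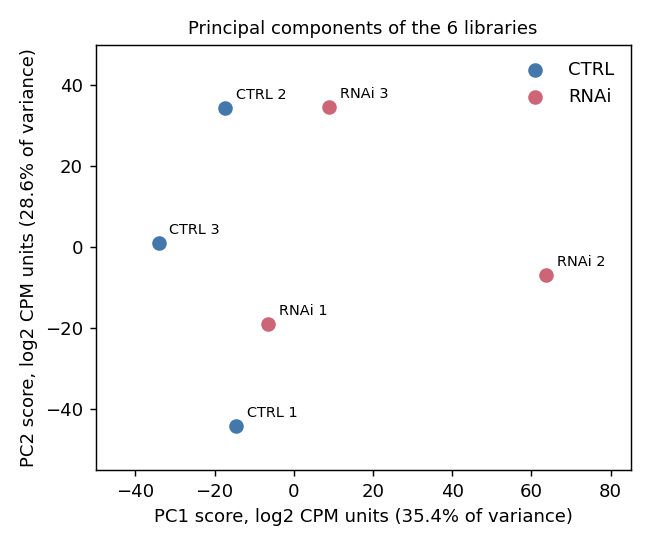
Scores of the 6 libraries on the first principal component (horizontal axis, 35.4% of variance) and the second (vertical axis, 28.6% of variance) of log2 CPM over the tested genes, CTRL in blue and RNAi in red. CTRL lies to the left of RNAi, with RNAi 2 far to the right, and the vertical axis places CTRL 2 beside RNAi 3.

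Genes with a large fitted difference were more often lower than higher in RNAi, with 41 lower by 4-fold or more and 13 higher by 4-fold or more. The second number was 21, 27 and 28 without CTRL 1, CTRL 2 and RNAi 1, and 7 by limma-voom. The 41 lower genes lay on 17 of the 20 chromosome groups, with 9 on chromosome 1 and 9 on chromosome 19, where their shares of the tested genes give 4.67 and 1.11. Of the 41, 15 lay within 5 tested genes of another of the set, against at most 8 in 10000 random sets of tested genes. The random sets ignore that neighbouring genes can vary together. Other groupings of the libraries were not counted this way, so the closeness is not tied to RNAi. CTRL and RNAi values did not overlap in 38 of the 41, where chance gives 10% among genes not picked for their difference. RNAi 1 had the highest level of the RNAi libraries in 34 of the 41. Relative to the CTRL mean, the median of the 41 genes was -1.63 in RNAi 1, -3.49 in RNAi 2 and -3.13 in RNAi 3 on the scale of log2 CPM with a prior count of 2, on which values near 0 depend. The same median was 0.14 in CTRL 1, -0.51 in CTRL 2 and 0.33 in CTRL 3. For the 13 higher genes it was 1.66 in RNAi 1, 3.18 in RNAi 2 and 1.64 in RNAi 3. These sets were picked by their fitted difference, and 1 of the 54 genes passed the quasi-likelihood test.

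Genes that were silent in wild type and expressed in RNAi were about as many as the converse. Counts were 0 in all 3 CTRL libraries and above 0 in all 3 RNAi libraries for 31 genes, and 24 genes showed the reverse. Other arrangements of the 6 libraries into 3 and 3 gave between 9 and 44 such genes. With a minimum of 10 counts over the expressing group the numbers were 5 and 2, and with a minimum of 20 counts they were 1 and 2. The 1 gene left in the first class was Potri.018G050400.

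None of the 19 chromosomes, nor the group of genes on scaffolds, passed a test of a shift as a whole between RNAi and CTRL. Median log2 fold changes ranged from -0.02 on chromosome 16 to 0.03 for the 647 scaffold genes. By camera with a preset correlation no group passed, with a lowest adjusted p of 0.97 over the 20 groups. With an estimated correlation the lowest adjusted p was 0.55, for the scaffold genes, and with fry it was 0.99. At an unadjusted p under 0.05 in edgeR, 36 scaffold genes were higher and 14 lower. Higher genes also prevailed among all tested genes (769 and 641), on chromosome 5 (68 and 37) and on chromosome 13 (48 and 27). Chromosome 12 went the other way (19 and 28).

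A stretch of 13 neighbouring tested genes on chromosome 13, from Potri.013G120700 to Potri.013G122900, held the strongest run of differences in the same direction in a scan chosen after seeing the data. Fitted levels were higher in RNAi for 11 of the 13, with a median log2 fold change of 0.64 (1.56-fold). The values ranged from -0.24 ± 0.53 to 1.51 ± 0.32 (SE), and in 9 of the 13 all 3 RNAi libraries lay above all 3 CTRL libraries, where chance separates the groups, in either direction, in 10% of genes not picked for their difference as these were by the scan. The 10 tested genes on either side, 20 in all, had a median of -0.08. Relative to the CTRL mean, the median of the run was 0.71, 0.53 and 0.88 in RNAi 1, 2 and 3 and between -0.10 and 0.11 in the CTRL libraries. None of the 13 passed edgeR's quasi-likelihood test after adjustment over all genes, and 8 had an unadjusted p under 0.05. The scan statistic was 7.94, above the highest of 1000 random gene orders (5.91). One of the other 9 divisions of the 6 libraries into 3 and 3 gave a higher value, 8.12, for 5 genes on chromosome 19. The rest gave 7.25, 6.38, 6.33 and 6.01, also above all random orders, and 5.61, 5.34, 5.13 and 4.95, below the highest of them.

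**Figure D3:**
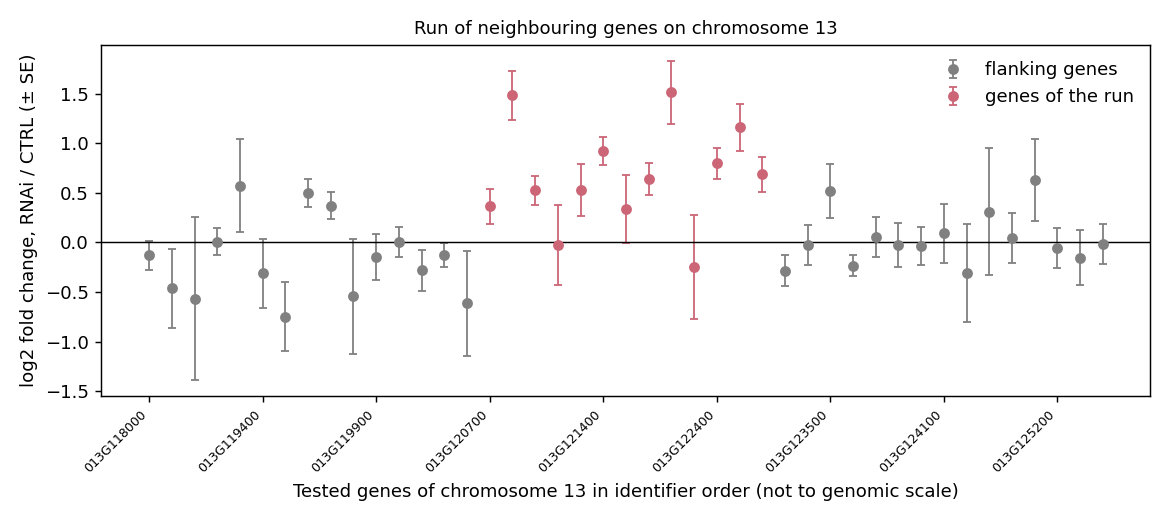
Fitted log2 fold change of RNAi over CTRL (vertical axis, points with SE bars) for tested genes of chromosome 13 in identifier order (horizontal axis, not to genomic scale), the 13 genes of the run in red and 15 flanking genes on each side in grey. In the run 11 of 13 values lie above 0, up to 1.51.

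Shares of reads not assigned to a gene, among which transcripts of unannotated transposons would fall, overlapped between the RNAi and CTRL libraries. The permutation test could not have found a difference in them, since 3 against 3 libraries cannot reach a p below 0.10. Reads without an annotated feature on their strand, which include reads opposite to genes, made up 3.86 ± 0.15% of all reads in RNAi and 4.00 ± 0.19% in CTRL (SD, n = 3 each, exact permutation p = 0.40). Reads without a feature on either strand made up 3.15 ± 0.16% in RNAi and 3.26 ± 0.21% in CTRL (exact permutation p = 0.60, outside the adjustment over read classes). Multimapping reads, which include those of repeated sequences, made up 3.77 ± 0.19% in RNAi and 3.63 ± 0.23% in CTRL (exact permutation p = 0.70). Unmapped reads were 3.61 ± 0.21% and 3.95 ± 0.78% (exact permutation p = 0.70), and ambiguous reads 0.689 ± 0.060% and 0.674 ± 0.034% (exact permutation p = 0.60). Counts on the strand opposite to the gene were 1.62 ± 0.03% of stranded gene counts in RNAi and 1.75 ± 0.07% in CTRL, with all 3 RNAi libraries below all 3 CTRL libraries. The exact two-sided permutation p for this share was 0.10, the smallest that 3 against 3 libraries allow, and 0.50 after adjustment over the 5 read classes. The other 4 classes had an adjusted permutation p of 0.70.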

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

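The test of leakage from the sense transcript and the count over splits were chosen after the result was seen. Counts on the strand opposite to the gene, which the comparison of sense counts does not use, held 1 gene above the CTRL level. Potri.004G129800, named after its values were seen, had 3, 3 and 2 opposite-strand counts in CTRL and 36, 112 and 27 in RNAi, a log2 fold change of 4.31 ± 0.64 (SE, adjusted p = 0.040 in edgeR's quasi-likelihood test over 1725 genes with enough such counts). It was higher in 3 of 3 RNAi libraries, and no gene was lower, with 112 genes at an unadjusted p under 0.05. Of the 10 splits of the 6 libraries, 2 gave at least 1 gene, the highest of the others also 1, and 10 splits are too few for a share under 0.05.

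Leakage of reads from the gene's own sense transcript is argued against by the sense counts, whose log2 fold change was -0.034 ± 0.14. Read-through from an adjacent gene stays open. The highest log2 fold change of the 4 nearest listed genes was 0.266 ± 0.13, under the bound of 1 set beforehand. That bound left out the level of this neighbour, Potri.004G129900, which differed by 5.41 CPM (32.2 ± 2.83 against 26.7 ± 2.09, SD, n = 3 each). The opposite strand differed by 3.58 CPM (3.78 ± 2.99 against 0.196 ± 0.0688). RNAi 2 had the most opposite-strand counts (112, against 36 and 27 in RNAi 1 and 3) but the fewest RNAi counts of the neighbour (475, against 490 and 531). These values argue against read-through in a fixed share of the neighbour's level. A change in that share was not tested. Also open, and not tested, is a transcript of the opposite strand that no listed neighbour accounts for. The same holds for reads from a sequence that resembles this gene, or a difference that comes with the RNAi plants for another reason. No sequence was used with which these could be told from one another.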

How the results depend on the processing

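The count of 1 changed gene varied with the test. DESeq2 called 37 genes with its own filtering and 38 on the genes that edgeR tested, edgeR's likelihood ratio test 61 and limma-voom 2, each with Potri.016G130900 among them. No gene was called with library size as the only scaling, at least 1 CPM in 3 libraries, the replicate block or 1 surrogate variable (0 genes each), where edgeR's adjusted p of Potri.016G130900 was 0.0564, 0.0501, 0.102 and 0.0934. Its log2 fold change was 6.97, 7.01, 7.04 and 7.06 there, and the cause was not tested. The surrogate variable, the second DESeq2 fit and the fit that was not robust were chosen after seeing the data. Leaving out 1 library, with fewer libraries to test, gave between 0 and 7 genes, the 7 without RNAi 1. RLE factors, upper-quartile factors, no filter, an added log2 fold change of at least 1, the unstranded column and a fit that was not robust each gave 1 gene, Potri.016G130900, and the forward column gave 1 other gene. Over its 19 alternatives Potri.016G130900 kept a log2 fold change between 6.32 and 8.94, with adjusted p from 3.441e-24 to 0.67. The other 3 named genes kept their direction wherever tested (Potri.018G050400 was not tested under the 1 CPM filter) but not their size. Log2 fold changes lay between 4.99 (limma-voom) and 7.13 for Potri.018G050400, -8.21 and -3.82 (unstranded column) for Potri.016G070100, and -6.70 and -3.27 for Potri.019G008300. Potri.018G050400 passed with DESeq2, the likelihood ratio test and limma-voom, Potri.016G070100 with DESeq2 and the likelihood ratio test and Potri.019G008300 with the likelihood ratio test, with adjusted p over their alternatives from 2.528e-09, 1.657e-06 and 0.028, each up to 0.9998. Deviations from the group means correlated by 0.24, -0.02 and -0.03 between libraries numbered 1, 2 and 3, and CTRL 2 correlated best with RNAi 3 (0.42), so the block of replicate numbers is no paired analysis. The difference in unmapped share lay between -0.674 and 0.0866 percentage points with 1 library left out, turning sign without CTRL 2, and that of ambiguous reads between -0.00373 and 0.0496, turning sign without CTRL 3, RNAi 1 or RNAi 3. The other 3 read classes kept their direction but not their size, between 0.0420 and 0.269 for multimapping reads, -0.217 and -0.0369 for reads without a feature (-0.109 by the unstranded column) and -0.162 and -0.0880 for the opposite strand. Genes with a fitted change of 4-fold or more numbered between 44 and 77, with more lower than higher in each alternative. The median of the chromosome 13 run stayed between 0.55 and 0.77. Alternatives planned for DDM1, gene lists and transposon-derived genes were not run, for lack of gene names.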

Other observations

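The scan for runs was chosen after seeing the data, and the tests chosen only after the result was seen were the splits for the likelihood ratio test and for 4-fold changes, the depth ratio, the range within CTRL, the heterogeneity of folds and the held-out counts. The division by genotype was not the one that called most genes among these 6 libraries. Grouping CTRL 1, RNAi 1 and RNAi 2 against CTRL 2, CTRL 3 and RNAi 3 gave 6 genes in edgeR's quasi-likelihood test against 1 for the real groups, and 681 against 61 in the likelihood ratio test. Grouping CTRL 1, CTRL 3 and RNAi 1 against the rest gave 0 and 439. The numbers of splits with as many genes as the real one were 2 of 10 and 3 of 10, and 10 splits are too few for a share under 0.05. The 2 pairs of libraries with the lowest chi-square per degree of freedom each joined a CTRL and an RNAi plant. They were CTRL 1 with RNAi 1 (8.31) and CTRL 2 with RNAi 3 (14.6). Pairs within a group gave 15.4 to 37.6, and the remaining mixed pairs 17.25 to 40.9. A structure of the samples that crosses the genotypes is possible. Neither the splits nor these pairs, which were not tested, can tell it from chance, and the labels name no batch. The number of genes with a fitted change of 4-fold or more went the other way, with 54 for the real groups and at most 33 for the other splits (1 of 10 as large).

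The genes with a fitted fall of 4-fold or more may in part mark variation between plants that both genotypes share. The RNAi libraries were on average not the shallower ones, with a mean assigned total 1.13 times that of CTRL. The fitted folds are scaled for library size, so this ratio says little about the falls. Among CTRL plants alone, the 41 genes had a median range of 1.26 on the log2 scale. This lay above all 10000 expression-matched random sets (percentile 100, median of the sets 0.57). These sets were drawn gene by gene, while 15 of the 41 genes lie close to another of them. The sets were also not picked by a fitted fold, as the 41 genes were, which by itself favours a wide range. The comparison therefore cannot show that both genotypes share this variation. In RNAi, not compared with such sets, the median range was 2.405. CTRL 2 was the lowest CTRL library in 32 of the 41, and RNAi 1 the highest RNAi library in 34. A difference of genotype on top of this variation stays open, since genes with large spread are more readily picked by a fitted fold.

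The run on chromosome 13 is a candidate for a local difference between the groups. Random placement of changed genes is argued against, with a share of 0.001 of random gene orders, the smallest that 1000 orders can give. This does not tie the run to the genotype. Divisions that mix the genotypes also gave runs above the highest random order (5.91), from 6.01 to 8.12, while others gave 4.95 to 5.61. One common fold for all 13 genes is argued against by a heterogeneity p of 0.000321 (chi-square 36.0 on 12 degrees of freedom). That test takes the SEs as exact and the genes as independent. A change in copy number of the stretch stays open, since transcript levels need not follow it by the same fold in every gene. Neighbours that vary together in both genotypes stay open: the within-group correlation of the run (mean 0.152) lay at percentile 93.5 of 1853 other windows, and 2 of the 10 splits gave a run as strong (real 7.94, highest other 8.12), too few splits for a share under 0.05. Whether the difference reaches beyond the tested genes also cannot be told. Counts of the interval that the tested genes leave out, on the opposite strand or in untested genes, were 1.86 times higher in RNAi with no overlap. Without the 1 gene that gave 189 of these 400 counts the ratio was 1.41 and the groups overlapped. Most of the 400 were opposite-strand counts (30, 34 and 49 in CTRL 1, 2 and 3, and 74, 77 and 90 in RNAi 1, 2 and 3). These include the opposite strand of the tested genes themselves. Leakage of sense reads from those genes, mostly higher in RNAi, was not tested here.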
